A study of Homo sapiens with 8 samples.

How the data were processed

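Gene expression was measured in 8 samples of HepG2 cells treated with dimethyl alpha-ketoglutarate. Of these, 2 were untreated (0 h) and 1 each was taken at 3, 6, 9, 12, 24 and 48 h. The labels state that the compound was added at different times, and whether addition was staggered or cells were harvested in sequence was left open. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, amplified and labelled with the Agilent Quick Amp kit, and hybridised to Agilent arrays. The labels name the dye as Cy3 or Cy5, and per the file headers each array was scanned in 1 channel. All 8 arrays lay on 1 slide, scanned on 1 day, with the 0, 3 and 6 h samples in slide column 1 and the 9, 12, 24 and 48 h samples in slide column 2. Within each column the arrays lay in order of time. Both untreated samples are described as replicate 1 in the labels, while their titles end in 1 and 2. They are called replicates 1 and 2 here, after the titles.

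Per the submitters' processing notes, the authors extracted the deposited intensity values from the scans with Agilent Feature Extraction 11.0.1.1. Per the file headers, the processed signal is a background-subtracted intensity on a linear scale. Each array holds 62976 spots, of which 2075 are controls, and the others belong to 58201 probes. Control spots and spots marked as outliers in the files were left out, and the remaining spots of a probe were averaged. The probes' accessions were matched to gene symbols through the reference gene table, which served for names alone, since its genome build differs from that of the array design and no coordinates were used. A symbol was found for 31104 probes and none for 27097, and 0 probes had several. Probes of near-identical families, such as the AKR1C, CYP3A, UGT2B, HSPA1A and histone genes, may bind more than 1 transcript.

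Values were log2 of the processed signal minus the 75th percentile of the array, and the 75th percentiles were 195, 206, 134, 199, 197, 166, 186 and 224 from 0 to 48 h. Probes well above background on at least 2 arrays were kept (26678), with the brightest probe standing for each gene, which left 21742 genes or unnamed targets, 14257 of them with a symbol. The share of probes well above background was 41.8% to 45.5% per array, and the spread between spots of a probe within an array was 0.0489 to 0.0586 (log2), so the spots measured bright genes closely and the number of samples limits the precision.

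Arrays were grouped as untreated, early (3 and 6 h), middle (9 and 12 h) and late (24 and 48 h), 2 arrays in each, and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom). Early, middle and late were each tested against untreated, and late against early. A separate limma fit tested the slope per unit of log2(hours + 1) over all 8 arrays (6 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The p-values measure the spread between these samples alone. In the window fit, that spread includes the difference between the 2 times of each treated window. A change between those 2 times therefore counts as spread and not as an effect. The fits were tested on simulated data, in which the late fit found 53 of 100 genes changed by log2 1 and called 6 of 21542 unchanged genes, and the trend fit found 58 of 100 and called 5 of 21542. The simulated genes varied independently of each other, with the same spread on every array. For a gene well above background on no array of 1 of the 2 groups compared, the change is given as at least N-fold, where each array of the dim group is first raised to the lowest level at which any probe was well above background on that array, unless its own level is higher.

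Gene lists, 38 in number, were fixed before the data were examined, with 949 names of which 54 were not current symbols. Each of these was brought to the current symbol where a single match was found, and was left out otherwise. Metabolic lists were cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and ketogenesis, the TCA cycle and glutamate metabolism, oxidative phosphorylation, glycolysis, gluconeogenesis, the urea cycle and amino acid catabolism, drug and bile acid metabolism, and 2-oxoglutarate-dependent dioxygenases. Stress lists were the amino acid response (ATF4 targets), endoplasmic reticulum chaperones, the heat shock response, NRF2, HIF, p53 and aryl hydrocarbon receptor targets, metallothioneins, ferroptosis regulators, cell death genes, and lysosome and autophagy genes. Growth and signalling lists were G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, ribosomal proteins, ribosome biogenesis and MYC targets, immediate early genes, NF-kB and acute phase genes, the interferon response, YAP/TEAD targets, and epithelial-mesenchymal and matrix genes. Identity lists were secreted liver proteins, liver transcription factors, oncofetal liver and Wnt targets, and markers of endothelial, leukocyte, fibroblast and stellate, and cholangiocyte and keratinocyte cells. The 37 lists with at least 5 measured members were tested with camera (preset correlation 0.01), with an estimated correlation between genes and with fry as alternatives. Camera compares a list with all other genes, whereas fry asks whether the members of a list move on balance in 1 direction. Members are also given where their p passed a threshold adjusted over the list alone. List medians at single times were ranked among 10000 random lists of like expression.

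The rule for named genes took those past the adjusted threshold whose arrays all lay on the same side of the reference arrays (for the trend, with a rank correlation with time of at least 0.7), up to the 12 largest rises and falls in the late window and the 6 largest in each other comparison. Where fewer than 5 passed in a direction, the same number were taken by size alone and given as values. It also took up to 4 members of each list with the lowest p in the late window. List members named in the early, middle and late against early comparisons, and other members beyond those 4, were chosen after their values were seen. Unnamed targets were tested but not described, and of the genes taken by size the text gives a part. Some genes that the rule took or the lists hold are not reported here by name.

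Alternatives planned before the data were examined were normexp background correction (offset 50, on the median signal because the mean signal was absent) with quantile normalization, quantile normalization alone, centring on the median, no filter on dim probes, a filter on all 8 arrays, the mean over a gene's probes, eBayes with trend and robust settings, other time scales and groups, and leaving out each array. Chosen after seeing the data were counting the untreated arrays as 1, array brightness as a covariate, slide column as a block, and exact permutation of list means and of principal components. Tables and figures used the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.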

Results

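Gene expression was followed in HepG2, a human liver cancer cell line, after addition of dimethyl alpha-ketoglutarate, a membrane-permeable ester of alpha-ketoglutarate. Alpha-ketoglutarate, also called 2-oxoglutarate, is an intermediate of the TCA cycle and a cosubstrate of many dioxygenases. The study asked how the transcriptome changed with the duration of treatment. Total RNA from 8 samples was hybridised to 8 single-colour Agilent arrays. Of these, 2 were untreated (0 h) and 1 each was taken at 3, 6, 9, 12, 24 and 48 h. Because each treated time had 1 array, neighbouring times were tested together as an early window (3 and 6 h), a middle window (9 and 12 h) and a late window (24 and 48 h), each of 2 arrays against the 2 untreated arrays. No untreated sample from a later time was among the 8. If cells were harvested in sequence, treatment and time in culture were therefore not separated by the design. Staggered addition with a common harvest would give all samples the same time in culture, and the labels leave this open.

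The 75th percentile of the processed signal was 195 and 206 on the untreated arrays. It was 134 at 3 h, 199 at 6 h, 197 at 9 h, 166 at 12 h, 186 at 24 h and 224 at 48 h, so the 3 h array was the dimmest before scaling. Between 41.8% and 45.5% of the 58201 probes were well above background, and 0 probes were saturated. The 2 untreated arrays differed by an SD of 0.0786 (log2) over 10876 bright genes, against 0.0747 from spot scatter alone, while every other pair of arrays differed by 0.171 to 0.466. Over 270 probes printed 10 times each, the untreated pair differed by an SD of 0.0427 against 0.0236 from spot scatter, a difference that 1 RNA hybridised to 2 arrays could also give. Whether they are 2 cultures or 1 RNA is not known from the labels. They were treated as 2 samples, and if they share 1 RNA, every SE and p that rests on them understates the spread between cultures. The number of arrays limits the precision of every value that follows.

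Genes of sterol and fatty acid synthesis fell with time of treatment. All 25 measured members of the cholesterol synthesis and uptake list (SREBP2 targets) had a negative slope against log2(hours + 1), with a median of -0.102 log2 per unit, and 17 of them passed a threshold adjusted over the list alone. All 17 measured members of the fatty acid synthesis list also had a negative slope, with a median of -0.091, and 9 passed over the list alone. Among the camera calls these 2 held with an estimated correlation between genes, and both were lost when array brightness was added as a covariate under that correlation (adjusted p = 0.126 for each). The adjusted p was 1.8e-22 for cholesterol and 2.05e-13 for fatty acids with the preset correlation, and adjusted p = 0.0261 with an estimated correlation for each.

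NRF2 targets, genes of the oxidative stress response, rose with time, with 20 of 23 slopes positive and a median of 0.058 (camera adjusted p = 1.32e-07; adjusted p = 0.186 with an estimated correlation). With slide column as a block this call was lost (median 0.049, adjusted p = 0.104). Drug and bile acid metabolism fell, with 11 of 12 slopes negative and a median of -0.093 (3.08e-06; adjusted p = 0.186 with an estimated correlation). That call was also lost with slide column as a block (median -0.034, adjusted p = 0.477). Its median was -0.047 without the filter on dim probes. Its list mean correlated with time with a Pearson r of -0.866 (exact permutation p = 0.00521, adjusted over 38 lists 0.0495). With the untreated arrays counted as 1, r was -0.858 (exact permutation p = 0.00536, not adjusted), so the adjusted value just under 0.05 is fragile. Within the slide columns r was -0.361 and -0.639. ATF4 targets of the amino acid response had negative slopes in 28 of 29 members (median -0.067, adjusted p = 1.32e-07; adjusted p = 0.561 with an estimated correlation), and endoplasmic reticulum chaperones in 21 of 23 (median -0.047, 6.84e-05; adjusted p = 0.496 with an estimated correlation). Neither list kept falling among the treated arrays: the mean of the ATF4 list was -0.57 at 3 h and -0.35 at 48 h, and that of the chaperones -0.25 and -0.18. The ATF4 slope shrank to -0.035 and -0.030 without untreated replicate 1 or 2. Further shifts passed for HIF targets (median 0.035, adjusted p = 0.000564), the G1/S and DNA replication list (-0.026, 0.000652), replication-dependent histones (-0.052, 0.00275) and the TCA cycle list (-0.016, 0.0153). For these 4 lists the adjusted p with an estimated correlation was 0.607, 0.62, 0.879 and 0.561. Without the 48 h array they no longer passed (adjusted p = 0.953 for HIF targets, 0.182 for G1/S, 0.611 for histones and 0.182 for the TCA cycle), and the TCA cycle list was also lost without either untreated array (0.0586 and 0.0623) and with quantile normalization (0.173). With brightness as a covariate the median slope was 0.023 for HIF targets and -0.032 for histones. Rearranged orders of the arrays gave a median of 8 lists past the preset correlation for the trend, against the real 10.

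At the level of single genes, limma called 1 of 21742 genes for a trend. SECTM1, which encodes a secreted and transmembrane protein of immune signalling, fell with a slope of -0.345 (SE 0.029, adjusted p = 0.0318). Against the untreated mean its log2 level was -0.56 at 3 h, -1.04 at 6 h, -1.16 at 9 h, -1.57 at 12 h, -1.64 at 24 h and -1.78 at 48 h. When each array was left out in turn the adjusted p of SECTM1 ran from 0.023 to 0.268 and passed in 2 of 8 fits, those without the 3 h and without the 12 h array. At an unadjusted p under 0.05 there were 1682 genes, a count that 19 of 100 orders of the arrays, the real one among them, reached. Among rises that were not calls, the largest slopes included PDGFRB, the receptor for platelet-derived growth factor (0.368, SE 0.0475, adjusted p = 0.111), IGFBP1, a liver-secreted binding protein for insulin-like growth factors (0.373, SE 0.123, adjusted p = 0.486), and CLIC3, a chloride channel protein (0.33, SE 0.0731, adjusted p = 0.287; 0.199 with slide column as a block). Several falls that were not calls were steeper, such as BDNF-AS (-0.511, SE 0.175, adjusted p = 0.506).

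**Figure D1:**
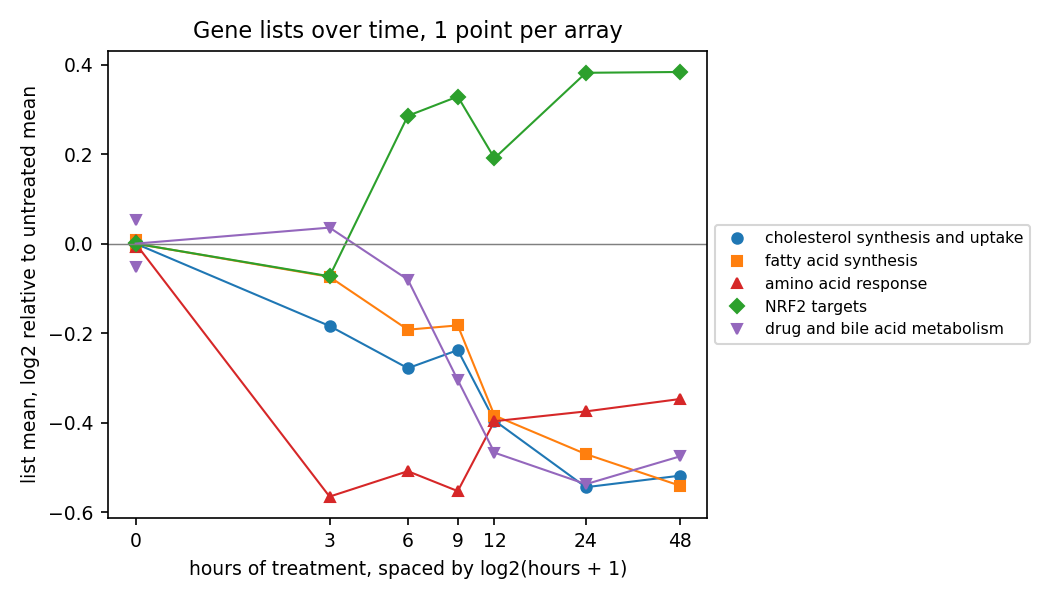
Mean log2 level of 5 gene lists on each of the 8 arrays, relative to the untreated mean (vertical axis), against hours of treatment spaced by log2(hours + 1) (horizontal axis), with 1 point per array and both untreated arrays at 0 h. The cholesterol and fatty acid lists lie lowest at 24 and 48 h, while the amino acid response list is already low at 3 h.

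In the early window, genes that ATF4 induces under amino acid shortage fell together. Of 29 measured members 27 were lower than in untreated cells, with a median log2 change of -0.41, and 17 were lower with p-values adjusted over the list alone. The following members were chosen after their values were seen. CHAC1, a glutathione-degrading enzyme, changed by -1.87 (SE 0.38), ASNS, asparagine synthetase, by -1.02 (SE 0.23), DDIT3, which encodes the stress factor CHOP, by -0.97 (SE 0.155), STC2, a stanniocalcin, by -1.10, and SESN2, a sestrin, by -0.68. Without the 3 h array STC2 stood at -0.72. The camera adjusted p of the ATF4 list was 3.75e-12 with the preset correlation, adjusted p = 0.395 with an estimated correlation, and 0.0204 by fry.

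Other lists moved in the same window. Nuclear subunits of oxidative phosphorylation were lower (29 of 32 members, median -0.16, camera adjusted p = 0.000144), as were p53 targets (22 of 27, median -0.26, 0.000247), including PMAIP1, a BH3-only death gene, at -0.69. For both lists the adjusted p was 0.0308 by fry and adjusted p = 0.395 with an estimated correlation. The cholesterol list was lower (20 of 25 members, median -0.29, adjusted p = 0.000247; adjusted p = 0.465 with an estimated correlation), and so were endoplasmic reticulum chaperones (19 of 23, median -0.22, 0.00123; adjusted p = 0.395 with an estimated correlation). Secreted liver proteins were higher in 22 of 35 members (median 0.15, adjusted p = 0.00787; adjusted p = 0.605 with an estimated correlation), with FGA, the fibrinogen alpha chain, at 0.65 and ITIH4, an acute phase protein, at 0.74 (p-values adjusted over the list alone). Targets of the aryl hydrocarbon receptor were higher in 5 of 6 members (median 0.43, adjusted p = 0.036; adjusted p = 0.395 with an estimated correlation), and the 1 member past over the list alone was ALDH3A1, an aldehyde dehydrogenase, at 1.02.

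Smaller early falls passed for ribosome biogenesis and MYC targets (median -0.14, adjusted p = 0.0225), the heat shock response (-0.12, 0.0352), 2-oxoglutarate-dependent dioxygenases (-0.11, 0.036) and the G2/M list (-0.11, 0.0402). For these the adjusted p with an estimated correlation was 0.395, 0.395, 0.465 and 0.395. Among single genes limma called 0 of 21742 in the early window, with 3744 at an unadjusted p under 0.05. The lowest adjusted p of a gene with a symbol belonged to TAMALIN, a neuronal scaffold protein, which stood at -1.37 (SE 0.09, adjusted p = 0.0547), a value chosen after it was seen. Ranked by size alone, FST, the activin-binding protein follistatin, was higher by 2.31 (SE 0.33) and CYP24A1, the vitamin D-inactivating enzyme, at least 3.21-fold (adjusted p = 0.179). ANGPTL8, a hepatic regulator of lipoprotein lipase, stood at -2.11 (SE 0.66) and EMP1, an epithelial membrane protein, at -2.01 (SE 0.83). Without the 3 h array ANGPTL8 stood at -1.17 and EMP1 at -1.10, and without the 6 h array the log2 difference of CYP24A1, not a measured size, went from 2.60 to 0.94. Without the 3 h array, 4 of the early calls were lost (adjusted p = 0.368 for dioxygenases and G2/M, 0.0851 for heat shock and 0.0907 for ribosome biogenesis), and the same 4 were lost without untreated replicate 2 (0.0585, 0.0878, 0.0794 and 0.0585). Quantile normalization also ended them (0.0983 for dioxygenases, 0.365 for G2/M, 0.0744 for heat shock and 0.137 for ribosome biogenesis). The secreted protein call was lost without the 6 h array (0.324), and the aryl hydrocarbon receptor call without the 6 h array (0.132) or untreated replicate 1 (0.0661).

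In the middle window all 29 measured ATF4 targets were lower than in untreated cells, with a median of -0.37, and 11 were lower with p-values adjusted over the list alone. Members chosen after their values were seen included CHAC1 at -1.67, STC2 at -1.22, DDIT4, a stress-induced inhibitor of mTOR signalling, at -1.06, JDP2, a basic leucine zipper factor, at -0.92 and SESN2 at -0.62. The camera adjusted p of this list was 1.1e-13, adjusted p = 0.243 with an estimated correlation, and 0.0349 by fry. Cholesterol genes were lower in 23 of 25 members (median -0.32, adjusted p = 1.42e-09; adjusted p = 0.454 with an estimated correlation) and fatty acid synthesis genes in 16 of 17 (median -0.36, 2.64e-05; adjusted p = 0.489 with an estimated correlation), among them the elongase ELOVL6 at -0.72. Drug and bile acid metabolism was lower in 9 of 12 members (median -0.40, 0.00074; adjusted p = 0.489 with an estimated correlation), with CYP3A5, a drug-metabolising cytochrome, at -1.12 and SLC51B, a subunit of a bile acid exporter, at -0.82. Without the filter on dim probes the median was -0.06 for drug and bile acid metabolism and -0.21 for fatty acid synthesis, and both still passed.

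Endoplasmic reticulum chaperones (21 of 23 lower, median -0.26, camera adjusted p = 3.05e-06; adjusted p = 0.454 with an estimated correlation) and p53 targets (23 of 27 lower, median -0.22, 4.34e-06; adjusted p = 0.243 with an estimated correlation) fell as well. NRF2 targets were higher in 19 of 23 members (median 0.16, 0.00174; adjusted p = 0.489 with an estimated correlation) and secreted liver proteins in 28 of 35 (median 0.14, 0.0037; adjusted p = 0.702 with an estimated correlation). Interferon response genes (median -0.15, 0.0175; adjusted p = 0.489 with an estimated correlation) and immediate early genes (median -0.21, 0.0484; adjusted p = 0.791 with an estimated correlation) were lower. The 9 h array decided 3 of these calls: without it the adjusted p was 0.496 for secreted proteins, 0.116 for interferon genes and 0.991 for immediate early genes, whose median turned to 0.010, and the last list was also lost without untreated replicate 1 (0.0601) or 2 (0.0763) and with quantile normalization (0.0514). Among single genes limma called 0 of 21742, with 2221 at an unadjusted p under 0.05 and a lowest adjusted p of 0.171 for TAMALIN. By size alone, CNN1, a smooth muscle calponin, was higher by 2.02 (SE 0.57) and DEPP1, a FOXO-induced autophagy gene, by 1.75 (SE 0.38), while FCGR2A, an Fc receptor, was at least 2.47-fold lower (adjusted p = 0.316).

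The late window held the strongest shift of lipid genes. All 25 cholesterol genes were lower than in untreated cells, with a mean log2 change of -0.53, and 19 were lower with p-values adjusted over the list alone. FDPS changed by -0.69 (SE 0.10), DHCR7, the last enzyme of cholesterol synthesis, by -0.72 (SE 0.11), LSS, lanosterol synthase, by -0.86 (SE 0.14) and ACAT2, a cytosolic thiolase, by -0.68 (SE 0.12). The camera adjusted p of the list was 9.84e-20, adjusted p = 0.281 with an estimated correlation, and 0.0211 by fry.

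All 17 fatty acid synthesis genes were lower in the late window as well, with a median of -0.44, and 9 were lower over the list alone. The desaturase FADS2 changed by -1.25 (SE 0.19), ELOVL6 by -0.71 (SE 0.09), ACSS2, which makes acetyl-CoA from acetate, by -0.78 (SE 0.14) and SREBF1, the gene of the lipogenic factor SREBP1, by -0.77 (SE 0.14), or -0.43 as the mean over its probes. FASN, fatty acid synthase, at -0.60 (SE 0.12), was chosen after its value was seen. By camera the adjusted p was 2.39e-12, adjusted p = 0.297 with an estimated correlation, and 0.0211 by fry.

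**Figure D2:**
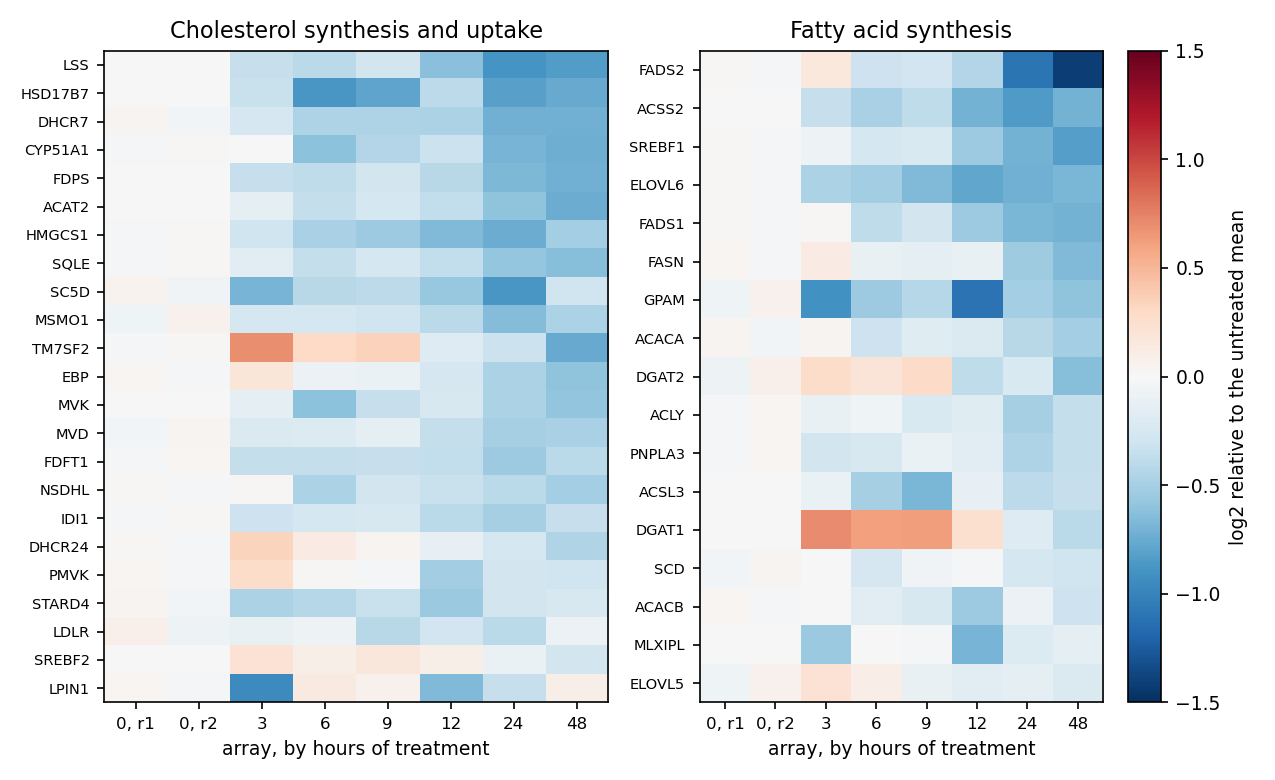
Heat maps of the log2 level of 23 of the 25 measured members of the cholesterol list (left) and all 17 of the fatty acid synthesis list (right) on each of the 8 arrays, relative to the untreated mean; columns are arrays by hours of treatment (r1 and r2 are the untreated replicates) and blue is lower. All 17 fatty acid genes are below the untreated mean at 24 and 48 h, while DGAT1 in that list and TM7SF2 in the cholesterol list are above it at 3, 6 and 9 h.

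NRF2 targets rose in the late window, with 20 of 23 members higher and a median of 0.30, and 5 passed over the list alone. AKR1C1, AKR1B10 and AKR1C3, aldo-keto reductases that detoxify carbonyls and steroids, changed by 1.03 (SE 0.10), 1.38 (SE 0.23) and 0.64 (SE 0.11). AKR1C probes may share sequence between family members, so the values of single AKR1C genes are uncertain. ABCC3, an exporter of organic anions, changed by 0.72 (SE 0.18) and OSGIN1, an oxidative stress response gene, by 1.15 (SE 0.31). With camera the adjusted p was 2.17e-07, adjusted p = 0.309 with an estimated correlation, and 0.0472 by fry. Genes of drug and bile acid metabolism fell (11 of 12 lower, median -0.44), with 5 past over the list alone. SULT2A1, which sulfates steroids and bile acids, changed by -1.41 (SE 0.12), UGT2B4, which glucuronidates bile acids, by -0.92 (SE 0.16), SLC51B by -0.84 (SE 0.14) and CYP3A7, a fetal liver cytochrome, by -0.68 (SE 0.15). The camera adjusted p was 2.13e-05, adjusted p = 0.323 with an estimated correlation, and 0.0211 by fry, and the median was -0.24 without the filter on dim probes.

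ATF4 targets stayed lower in the late window in 27 of 29 members (median -0.34), 9 of them over the list alone, with ALDH1L2, a mitochondrial folate enzyme, at -0.73 (SE 0.11), TRIB3, a stress-induced pseudokinase, at -0.66 (SE 0.14), JDP2 at -0.76 (SE 0.17) and AARS1, alanyl-tRNA synthetase, at -0.41 (SE 0.09). Camera gave an adjusted p of 7.52e-11, adjusted p = 0.281 with an estimated correlation, and 0.0211 by fry. Endoplasmic reticulum chaperones were lower in 21 of 23 members (median -0.27, camera adjusted p = 1.07e-05; adjusted p = 0.323 with an estimated correlation), with 0 past over the list alone. The TCA cycle and glutamate metabolism list was lower in 29 of 39 members (median -0.13, 0.00344; adjusted p = 0.354 with an estimated correlation), and IDH1, the cytosolic enzyme that makes alpha-ketoglutarate from isocitrate, changed by -0.62 (SE 0.09), the 1 member past over the list alone. HIF targets were higher in 20 of 24 members (median 0.21, 0.00344; adjusted p = 0.62 with an estimated correlation). Their list mean also went with array brightness, with a Pearson r of 0.831 (exact permutation p = 0.0145, adjusted over 38 lists 0.138) and a Spearman rho of 0.905 (exact permutation p = 0.00456, adjusted 0.0867). Without the 3 and 12 h arrays r was 0.804, and within the slide columns 0.909 and 0.87. The urea cycle and amino acid catabolism list was lower in 14 of 20 (median -0.11, 0.0487; adjusted p = 0.531 with an estimated correlation), with CBS, cystathionine beta-synthase, at -0.60 (SE 0.11).

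Cell cycle, respiratory and histone lists were also lower in the late window. G1/S and DNA replication genes (36 of 40 lower, median -0.13, camera adjusted p = 0.00344; adjusted p = 0.666 with an estimated correlation), G2/M genes (36 of 39 lower, median -0.09, 0.0266; adjusted p = 0.445 with an estimated correlation), oxidative phosphorylation subunits (31 of 32 lower, median -0.09, 0.0169; adjusted p = 0.531 with an estimated correlation) and histones (32 of 32 lower, median -0.24, 0.0169; adjusted p = 0.825 with an estimated correlation) fell. The histone list mean followed the brightness of the arrays, with a Pearson r of -0.923 against log2 brightness over the 8 arrays (exact permutation p = 0.000967, adjusted over 38 lists 0.0368). It stood at -0.02 at 24 h and -0.49 at 48 h, so the late fall rests on the 48 h array. Without the 48 h array 7 late calls were lost (adjusted p = 0.941 for HIF targets, 0.917 for histones, 0.129 for G1/S, 0.111 for G2/M, 0.0514 for the TCA cycle, 0.119 for oxidative phosphorylation and 0.27 for the urea cycle). The histone call was also lost without untreated replicate 1 (0.103), oxidative phosphorylation without replicate 1 (0.127), and G2/M without replicate 2 (0.114) or the 24 h array (0.0649). The urea cycle call was lost without untreated replicate 1 (0.0927), replicate 2 (0.0793), the 3 h array (0.0866) or the 6 h array (0.0899). Quantile normalization ended 5 late calls (adjusted p = 0.0637 for G1/S, 0.298 for G2/M, 0.568 for oxidative phosphorylation, 0.0839 for the TCA cycle and 0.141 for the urea cycle).

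**Figure D3:**
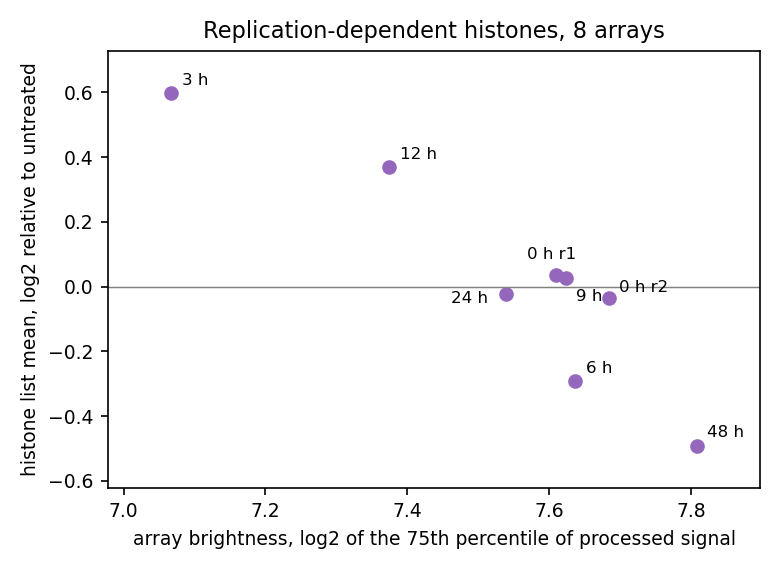
Mean log2 level of the histone list relative to the untreated mean (vertical axis) against log2 of the 75th percentile of the array (horizontal axis), with 1 labelled point for each of the 8 arrays. The dimmest array, 3 h, has the highest histone level and the brightest, 48 h, the lowest.

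The other 24 lists did not pass in the late window. Dioxygenases that use 2-oxoglutarate had a median of -0.04 (camera adjusted p = 0.917, 13 of 32 members higher), and glycolysis, gluconeogenesis, and fatty acid oxidation had medians of 0.08, -0.03 and -0.09. The gluconeogenesis mean was higher than its median, at 0.16 at 24 h and 0.25 at 48 h. By rank, the glycolysis and gluconeogenesis means rose with time (Spearman rho 0.922 and 0.91, exact permutation adjusted p = 0.0195 each). IGFBP1, among the 10 measured members of the gluconeogenesis list, stood at -1.16 at 3 h, 0.96 at 24 h and 2.28 at 48 h. The gluconeogenesis mean at 48 h thus rests largely on that gene, and its rise without IGFBP1 was not tested. Their Pearson r did not pass (adjusted p = 0.16 and 0.0811), and for glycolysis it was -0.313 within slide column 1. Fatty acid oxidation held members that moved apart: CPT1A, which admits fatty acids to mitochondria, changed by 1.17 (SE 0.25) and FABP1, the liver fatty acid-binding protein, by -0.99 (SE 0.11), both past over the list alone. Medians were -0.04 for secreted liver proteins, -0.14 for liver transcription factors, 0.11 for oncofetal and Wnt targets, -0.05 for p53 targets, 0.01 for the heat shock response and -0.04 for metallothioneins. They were 0.15 for aryl hydrocarbon receptor targets, 0.19 for immediate early genes, -0.02 for NF-kB and acute phase genes, -0.14 for interferon genes, -0.12 for lysosome and autophagy genes and -0.11 for ferroptosis regulators. Cell death genes stood at 0.00, ribosomal proteins at -0.04, ribosome biogenesis at -0.07, YAP/TEAD targets at 0.05 and epithelial-mesenchymal genes at 0.15. Of the markers of other cell types, the endothelial (median -0.25), leukocyte (-0.10) and cholangiocyte and keratinocyte lists (-0.06) did not pass camera, and the fibroblast and stellate list, with 4 measured members, was not tested by camera. Single markers did rise over the list alone: PDGFRB (1.80) and RGS5 (0.70, with 1 of 2 probes in that direction) of the fibroblast and stellate list, and ESAM, an endothelial adhesion molecule, by 0.80 (0.50 without the 48 h array). RGS5 stood at 0.35 as the mean over its probes. The mean of the fibroblast and stellate list rose with time, with a Pearson r of 0.944 (exact permutation p = 0.000149, adjusted over 38 lists 0.00565) and a Spearman rho of 0.970 (exact permutation p = 0.000595, adjusted 0.0113). That mean is carried mostly by PDGFRB, as the other 2 members, DES and ACTA2, stood at -0.18 and 0.04.

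Among single genes limma called 0 of 21742 in the late window, with 2012 at an unadjusted p under 0.05, a count that 16 of 100 assignments of the arrays, the real one among them, reached. The lowest adjusted p was 0.116, a value shared by several genes that include AKR1C1, IL17B, IL21R and LIPG. On simulated arrays the late fit found 53 of 100 genes changed by log2 1 and 79 of 100 changed by log2 2. The simulated genes varied independently, with the same spread on every array. The real untreated arrays differed less than any other pair, and many real genes moved together with brightness. These shares may therefore not hold for the real arrays. By size alone, genes far above untreated included LCN15, a lipocalin, at 2.85 (SE 0.44), PDGFRB at 1.80 (SE 0.32), FST at 1.76 (SE 0.33), the long non-coding RNA LUCAT1 at 1.75 (SE 0.33) and COMP, a cartilage matrix protein, at 1.71 (SE 0.54). FZD7, a Wnt receptor, was at least 2.66-fold (adjusted p = 0.411) and CYP24A1 at least 2.5-fold higher (0.326). Genes far below included IL21R, the interleukin-21 receptor, at -2.09 (SE 0.19), IL17B, a cytokine, at -2.07 (SE 0.18), LIPG, endothelial lipase, at least 3.84-fold lower (adjusted p = 0.116), KLHDC7B at least 2.93-fold lower (0.169) and FCGR2A at least 2.78-fold lower (0.276).

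Late against early was tested directly, to tell whether lists differed between the windows. Cholesterol genes were lower late than early in 23 of 25 members (median -0.30, camera adjusted p = 3.91e-05; adjusted p = 0.482 with an estimated correlation) and fatty acid synthesis genes in 15 of 17 (median -0.33, 9.43e-05; adjusted p = 0.482 with an estimated correlation). Members past over the list alone, chosen after their values were seen, were FADS2 at -1.18, FASN at -0.60 and DGAT1, which makes triglyceride, at -0.96. All 12 drug and bile acid genes were lower late than early (median -0.44, 0.000509; adjusted p = 0.482 with an estimated correlation), while NRF2 targets were higher in 18 of 23 (median 0.25, 0.000188; adjusted p = 0.482 with an estimated correlation), with AKR1B10 at 1.64 and NQO1, a quinone reductase, at 0.44 (0.29 without the 3 h array).

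Secreted liver proteins lost their early rise. They were lower late than early in 25 of 35 members (median -0.18, camera adjusted p = 0.000575; adjusted p = 0.583 with an estimated correlation), and 11 passed over the list alone. Members chosen after their values were seen were KNG1, kininogen, at -1.38, APOC3, an apolipoprotein of triglyceride-rich particles, at -1.30, HPX, hemopexin, at -0.92, and the fibrinogen chains FGA at -0.78 and FGB at -0.73. Higher late than early were p53 targets (median 0.17, 0.00252; adjusted p = 0.482 with an estimated correlation), with TIGAR, a regulator of glycolysis, at 1.00 and MDM2, the ubiquitin ligase of p53, at 0.62 (0.35 as the mean over its probes), and the heat shock response (median 0.17, 0.00195; adjusted p = 0.482 with an estimated correlation), with the small chaperone CRYAB at 1.60. HIF targets (median 0.30, 0.000863; adjusted p = 0.592 with an estimated correlation), ATF4 targets (0.14, 0.0275; adjusted p = 0.566 with an estimated correlation), dioxygenases (0.13, 0.0419; adjusted p = 0.582 with an estimated correlation) and oxidative phosphorylation (0.07, 0.0419; adjusted p = 0.583 with an estimated correlation) were also higher. Histones (median -0.41, 0.00149; adjusted p = 0.777 with an estimated correlation), G1/S genes (-0.15, 0.0111; adjusted p = 0.777 with an estimated correlation) and urea cycle genes (-0.26, 0.0228; adjusted p = 0.566 with an estimated correlation) were lower.

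Single arrays decided several of these differences, and HIF targets, histones and dioxygenases also went with array brightness. The HIF and dioxygenase lists share KDM3A, EGLN1, EGLN3, P4HA1 and P4HA2, so their results are not separate from each other. For the dioxygenase list mean the Pearson r with brightness was 0.852 (exact permutation p = 0.0128, adjusted over 38 lists 0.138). Its Spearman rho was 0.619 (exact permutation p = 0.115, adjusted 0.485). With quantile normalization the dioxygenase call was lost (adjusted p = 0.07). Without the 3 h array the adjusted p was 0.341 for dioxygenases, 0.0733 for G1/S, 0.334 for HIF targets, 0.0602 for NRF2 targets, 0.203 for ATF4 targets, 0.284 for oxidative phosphorylation and 0.899 for histones, whose median turned to 0.055. Without the 48 h array it was 0.339 for HIF targets, 0.198 for histones, 0.21 for dioxygenases, 0.0768 for G1/S and 0.0677 for urea cycle genes, and without the 6 h array 0.183 for secreted proteins and 0.191 for urea cycle genes. Oxidative phosphorylation was also lost without untreated replicate 1 (0.062) or 2 (0.0617), the 9 h (0.0564), 12 h (0.0549) or 24 h array (0.209). Among single genes limma called 1 of 21742, with 4039 at an unadjusted p under 0.05. SLC6A18, an amino acid transporter, was lower late than early by -1.96 (SE 0.112, adjusted p = 0.0391), at least 1.43-fold, since it was not well above background on the late arrays. The call was lost in each of the 6 fits without 1 array that kept the gene (adjusted p = 0.086 to 0.62). By size alone, EMP1 was higher late than early by 3.02 (SE 0.83), LCN15 by 2.78 (SE 0.44) and the long non-coding RNA UCA1 by 2.44 (SE 0.58), and without the 48 h array EMP1 by 1.91 and UCA1 by 1.55, while DKK4, a Wnt antagonist, was at least 2.55-fold lower (adjusted p = 0.166).

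Each treated time was last compared with the untreated mean without a test, as each had 1 array. Counting genes well above background on all 8 arrays, 398 of 18543 differed by 2-fold or more at 3 h, 154 at 6 h, 121 at 9 h, 99 at 12 h, 88 at 24 h and 182 at 48 h, against 17 between the untreated arrays. Over all 21742 tested genes the numbers were 1050, 513, 483, 573, 421 and 588, against 357 between the untreated arrays. If the untreated arrays share the same RNA, their counts leave out the spread between cultures, and the excess at treated times need not come from treatment. At 3 h, 247 of the 398 were higher, and at 48 h 120 of the 182.

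**Figure D4:**
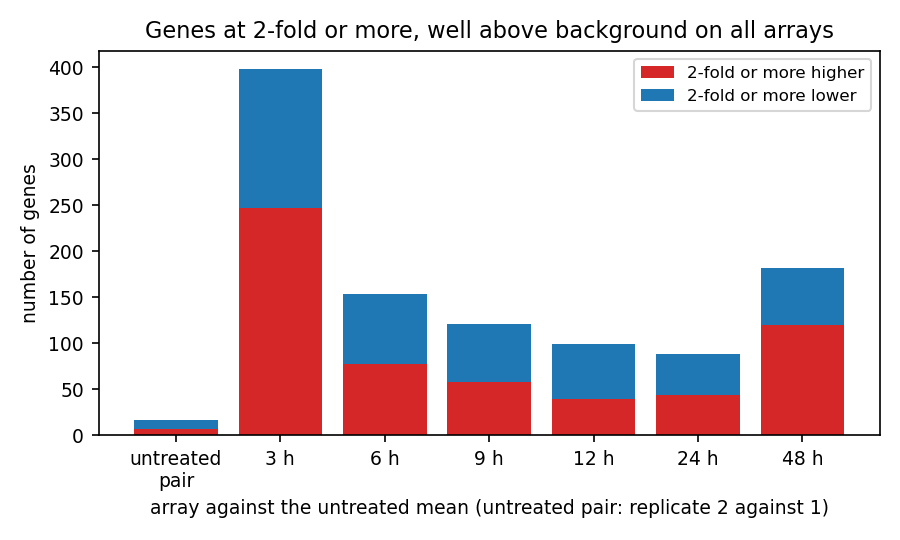
Number of genes (vertical axis) that differed by 2-fold or more from the untreated mean at each time, among 18543 genes well above background on all 8 arrays, with red for higher and blue for lower; the first bar compares the untreated arrays with each other. The 3 h array has the highest count (398) and the 24 h array the lowest of the treated times (88). The untreated arrays may share the same RNA, so the first bar may leave out the spread between cultures.

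Single time points placed the lists in order. The ATF4 list had a median of -0.61 at 3 h, -0.44 at 6 h, -0.54 at 9 h, -0.29 at 12 h, -0.32 at 24 h and -0.31 at 48 h, each below all 10000 random lists of like expression. Genes of the random lists were drawn independently, so a list whose genes vary together reaches such extremes more easily. Fatty acid synthesis stood at -0.00 at 3 h, -0.25 at 6 h, -0.23 at 9 h, -0.38 at 12 h, -0.46 at 24 h and -0.51 at 48 h. Secreted liver proteins stood at 0.17, 0.25, 0.25, 0.05, -0.00 and -0.08 at the same times. HIF targets were at -0.26 at 3 h and 0.47 at 48 h and between -0.08 and 0.09 at the other times. Immediate early genes were at 0.54 at 3 h, -0.44 at 9 h and 0.43 at 48 h, and histones at 0.64 at 3 h, -0.30 at 6 h, 0.40 at 12 h and -0.47 at 48 h.

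Resemblance between times did not simply follow their order, and the 3 and 12 h arrays, the 2 dimmest, were alike while the 3 and 48 h arrays, the dimmest and the brightest, were not. Across genes, which are not independent replicates, the log2 differences from untreated correlated with r = 0.696 between 6 and 9 h, 0.636 between 24 and 48 h, 0.605 between 9 and 24 h, 0.504 between 12 and 24 h, 0.436 between 9 and 12 h, 0.416 between 3 and 6 h, 0.601 between 3 and 12 h and -0.0406 between 3 and 48 h. Unchanged arrays set against the same 2 untreated arrays gave r = 0.334 in simulation, with a covariance of 0.00652, so part of each correlation may come from the shared controls. All simulated arrays had equal noise, sized from the untreated pair. Equal noise alone fixes the simulated r, so it is not the r to expect for the real arrays. The covariance was 0.0604 for 6 and 9 h, 0.0456 for 24 and 48 h and -0.00493 for 3 and 48 h. With a different untreated array for each time, r was 0.578 for 6 and 9 h, 0.499 for 24 and 48 h and -0.089 for 3 and 48 h. Component 1 of the 8 arrays, with 33.4% of the variance, correlated with log2 brightness with a Pearson r of 0.95 (exact permutation p = 0.00243, adjusted over 4 tests 0.00972), a Spearman rho of 0.667 (exact permutation p = 0.0831, adjusted 0.332), and r = 0.696 without the 3 and 12 h arrays. Within the slide columns r was 0.994 and 0.917. With time its r was 0.305 (exact permutation p = 0.488; rho 0.347, p = 0.397).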

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

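Of the tests in this part, the correlation of histones with G1/S genes was planned, and the tests on array brightness (with those of HIF targets, of dioxygenases and of component 1 given above), on quantile-normalized values and on immediate early genes were chosen after the result was seen. A direct test of late against early marked 1 gene and 14 lists as differing between the windows. SLC6A18 was at least 1.43-fold lower late than early (adjusted p = 0.0391); its log2 difference of -1.96 is not a measured size, as the gene was not well above background on the late arrays. Lower late than early were the median log2 values of cholesterol synthesis (-0.297), fatty acid synthesis (-0.334), drug and bile acid metabolism (-0.438), secreted liver proteins (-0.181), histones (-0.407), G1/S and DNA replication (-0.146) and the urea cycle (-0.26). Higher were NRF2 targets (0.246), HIF targets (0.301), the heat shock response (0.171), p53 targets (0.174), ATF4 targets (0.139), 2-oxoglutarate-dependent dioxygenases (0.13) and oxidative phosphorylation (0.069). With an estimated correlation between genes 0 of the 14 lists passed in camera. The count of 14 was not set against rearranged arrays.

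The 3 h array stood furthest from the untreated arrays and was the dimmest. After quantile normalization 1096 genes differed by 2-fold or more at 3 h against at most 559 at any other time, which argues against the brightness distribution of the array as the cause. With brightness and time in the same limma fit, 2212 genes passed for brightness and 0 for time (2424 at an unadjusted p under 0.05), and for brightness alone 2198 passed with all 8 arrays but 0 without the 3 h array (2632 unadjusted), so a profile that follows brightness was not told apart from that 1 array. Immediate early genes stood at percentile 100 of random lists of independently drawn genes at 3 h, which an early response to the compound and handling of the culture would give alike. Whether the 3 h profile came from the treatment, the culture or the RNA stays open with 1 array at that time.

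Histone genes moved together between single arrays, up at 3 and 12 h and down at 6 and 48 h. Their list mean correlated with log2 array brightness with a Pearson r of -0.923 (exact permutation p = 0.000967, adjusted over 38 lists 0.0368) and a Spearman rho of -0.905 (exact permutation p = 0.00456, adjusted 0.0867). Without the 3 and 12 h arrays r was -0.766, and within the slide columns -0.924 and -0.966, so a labelling or RNA state that follows brightness remains possible. With G1/S genes r was 0.536 (exact permutation p = 0.168; rho 0.405, p = 0.327), which left the share of cells in S phase undecided. Histone transcripts mostly lack a poly(A) tail, so priming could matter, and this stays open.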

How the results depend on the processing

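List results kept their direction in nearly every setting, while single-gene calls depended on the fit. Part of this was fixed in advance. The estimated correlation and fry use the same fitted changes, and leaving out an array outside a window comparison barely moves its median. The counts of list values are thus not counts of separate checks. Of 784 alternative values for lists, 604 kept their side of the threshold, 177 were weaker and 3 reversed. Of 2814 for named genes, 2736 were the same, 23 weaker, 53 stronger and 2 reversed. A gene value counted as the same if its sign and its side of the threshold were unchanged. Only SECTM1 and SLC6A18 were calls to begin with, so nearly all of these are non-calls that stayed non-calls. The count for genes thus says little about how stable their values were. The cholesterol list passed camera with the preset correlation in 13 of 13 settings for the trend (median slope -0.108 to -0.095), and so did fatty acid synthesis (-0.103 to -0.08). Where a lone array stood for a window, it was assumed to vary like the other groups. No paired analysis was possible because the groups share fewer than 2 replicate numbers. A block for slide or scan date was not run because all 8 arrays lay on 1 slide with 1 scan day. Signal over background limits dim genes most: without the filter on dim probes the number of 2-fold differences was highest. Counting the untreated arrays as 1 also ended the G2/M call early (adjusted p = 0.0512), the urea cycle call late (0.0524) and the oxidative phosphorylation call late against early (0.0608), and without the filter the urea cycle call late was lost (0.0848). For every value that moved, the cause was not tested.

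With normexp and quantile normalization limma called 15 genes for the trend (5 higher, 10 lower; 1 and all lower otherwise), 2 early, 1 middle, 14 late (2 higher, 12 lower) and 106 late against early (49 higher, 57 lower, 0 shared with the 1 gene reported). Under normexp 88 of 161 values for single genes were smaller by over 1.5 times. That setting changed the signal, background correction, offset and normalization together, and the part of each was not tested. With quantile normalization alone the counts were 2 for the trend, 1 early and 2 late against early. No filter on dim probes gave 0 for the trend and 0 late against early, and a filter on all 8 arrays gave 1 early, 4 late and 0 late against early. With trend and robust settings in eBayes they were 27, 1, 1, 25 and 10 for trend, early, middle, late and late against early. Hours on a linear scale gave 0 genes for the trend and the rank of time 10. Late against early gave 0 with only the 2 windows in the fit and 0 with each time its own group. Chosen after seeing the data, counting the untreated arrays as 1 gave 0 for the trend and 0 late against early, and brightness as a covariate and slide column as a block each gave 0 for the trend. The unadjusted counts beside these zeros are 2041 and 4266 (no filter), 3950, 2134, 2506, 8216, 1055, 2892, 2424 and 1229. Leaving out each array gave 0 to 3 genes for the trend and 0 to 0 late against early.

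Genes at 2-fold or more at 3, 6, 9, 12, 24 and 48 h numbered 108, 38, 26, 22, 22 and 61 with normexp (2 between the untreated arrays), 4014, 2844, 2398, 2371, 2317 and 2570 without the filter (2682 between the untreated arrays, above the counts at 9, 12, 24 and 48 h), and 398, 154, 121, 99, 88 and 182 with probes well above background on all 8 arrays (17 between the untreated arrays).

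Lists past camera with an estimated correlation numbered 2 for the trend, 0 early, 0 middle, 0 late and 0 late against early, and by fry 2, 3, 2, 5 and 7. With the preset correlation, under which 10 lists passed for the trend, 11 early, 10 middle, 13 late and 14 late against early, the numbers without the filter were 18 early and 16 middle, and with quantile normalization 8 late. For the trend 18 lists passed with slide column as a block, which kept 8 of the 10 and lost NRF2 targets (adjusted p = 0.104) and drug and bile acid metabolism (0.477), and 0 passed with brightness as a covariate and an estimated correlation. With the preset correlation, leaving out each array gave 8 to 12 for the trend, 8 to 14 early, 9 to 12 middle, 7 to 14 late and 8 to 14 late against early. The median of immediate early genes in the middle window turned from -0.210 to 0.010 without 9 h, though the direction by camera did not. Reversed were the histone slope without 48 h (0.012; range when each array was left out -0.087 to 0.012), HIF targets late without 48 h (camera direction turned, median 0.039; range 0.039 to 0.468), histones late against early without 3 h (0.055; range -0.875 to 0.055), and MID1 in the middle window without 9 h (-1.579) and without 12 h (-0.782; range -1.579 to 2.517).

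Other list medians that still passed moved by over 1.5 times. Early, they were -0.119 for endoplasmic reticulum chaperones and 0.245 for secreted proteins without 3 h, and -0.161 for dioxygenases without 6 h. Middle, they were -0.227 for fatty acid synthesis, -0.436 for immediate early genes and 0.247 for secreted proteins without 12 h, and -0.059 for interferon genes without the filter. Without 24 h they were 0.468 for HIF targets and -0.47 for histones late, and 0.197 for dioxygenases, -0.242 for G1/S, 0.515 for HIF targets, 0.157 for NRF2 targets and -0.641 for histones late against early. Late against early they were also -0.288 for drug and bile acid metabolism without the filter, -0.875 for histones without 6 h and -0.109 for secreted proteins without 48 h. For the trend they were -0.016 for G1/S with quantile normalization, and with slide column as a block 0.066 for HIF targets, -0.039 for the TCA cycle, -0.111 for ATF4 targets and -0.101 for histones. Without untreated replicate 2 they were 0.053 for HIF targets and -0.087 for histones, and with the untreated arrays counted as 1, -0.034 for ATF4 targets and -0.08 for histones.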

Other observations

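Of the tests in this part, the exact permutation of list means, brightness as a covariate and the slide column were chosen after the result was seen, and the regroupings and the order test were planned. Several genes outside the lists that passed also moved in the late window, with p-values adjusted over the list alone. CPT1A, which admits fatty acids to mitochondria, rose (log2 1.17) while FABP1, which binds fatty acids in the cytosol, fell (-0.99). CRYAB, a small heat shock protein, rose by 1.48 (SE 0.28) and MT2A, a metallothionein, by 0.50 (SE 0.11), while FLCN, a regulator of lysosomal signalling, fell (-0.51, SE 0.09). Among YAP/TEAD targets NT5E, an ectonucleotidase, fell (-0.71) and AXL, a receptor kinase, rose by 0.68. In the fibroblast and stellate list, which had 4 measured members, PDGFRB rose by 1.80, and its list mean correlated with time with a Pearson r of 0.944 (exact permutation p = 0.000149, adjusted over 38 lists 0.00565; rho 0.970, p = 0.000595, adjusted 0.0113). Without the 2 farthest arrays r was 0.896, and within the slide columns 0.926 and 0.749. The list mean is mostly that of PDGFRB, since DES and ACTA2 stood at -0.18 and 0.04 late, so it stands for little more than 1 gene. Genes chosen after their values were seen and not past the adjusted threshold were AKR1C8, an aldo-keto reductase relative, at 1.31 (SE 0.11) and PRSS8, a membrane serine protease, at -1.58 (SE 0.16).

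Cholesterol and fatty acid synthesis lists fell with time, though not at every step. The cholesterol list mean correlated with log2(hours + 1) with a Pearson r of -0.971 (exact permutation p = 0.000595, adjusted over 38 lists 0.00754) and a Spearman rho of -0.946 (p = 0.00129, adjusted 0.016), and without the 2 farthest arrays r was -0.921; for fatty acids r was -0.950 (p = 0.000546, adjusted 0.00754), rho -0.970 (p = 0.000595, adjusted 0.0113) and r without the 2 farthest -0.961. Brightness as a covariate left the median cholesterol slope at -0.098 against -0.102. Within the slide columns, each of few arrays, r was -0.999 and -0.846 for cholesterol and -0.945 and -0.905 for fatty acids. These values argue against brightness, or a difference between the 2 columns, as the cause. The adjusted p with an estimated correlation went from 0.0261 to 0.126 with brightness, however. Arrays lay in order of time within each column, so position along a column was not told apart from time. Of 100 orders of the arrays, the real one included, 1 reached the real 0.971, namely the real order itself, and 0.782 was the highest other. Time in culture without the compound stays open, since 0 untreated arrays came after 0 h and the labels do not say whether cells were harvested in sequence.

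Regrouping the arrays tested whether chance can be excluded for the counts. Each number that follows counts the real arrangement among the 100. Of 100 orders 40 gave as many lists for the trend as the real 10 (median other 8, highest other 18). Of 100 assignments 9 gave as many late lists as the real 13 (median other 8, highest other 15). As many genes for the trend as the real 1 came from 8 of 100 orders (highest other 77), so chance was not excluded for these 3 counts. Of the unadjusted counts, the 1682 genes for the trend were reached by 19 of 100 (highest other 4167) and the 2012 late genes by 16 of 100 (highest other 4893), so chance was not excluded for these either. The order with 77 genes correlated with array brightness at 0.719. List counts of the early and middle windows and of late against early were not regrouped, so chance was not tested for them. The 3 h difference had an SD of 0.308 over probes printed 10 times against 0.022 from spot scatter.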
